A study of Danio rerio with 6 samples.

How the data were processed

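RNA from pools of 25 larvae at 5 dpf was measured on Affymetrix zebrafish arrays, 1 array per sample, with 3 mutant and 3 phenotypically wild-type samples. Groups and replicate numbers came from the sample titles. The submitters' processing notes name RMA, without a version; RMA background-corrects and normalizes probe intensities and summarises them per probe set. The deposited values are standardized scores: on every array they had a median of 0 and a standard deviation of 1 over 15617 probe sets, with a lowest value of -2.10 and a highest of 4.17. The labels state neither this standardization nor the log base, so differences are given in array SD and no fold change is given. Hybridization spikes, at nominal amounts of the manufacturer's kit that are not in the sources used here, gave 2.00 to 2.16 doublings per array SD; this scale from 4 spikes is approximate and was not applied to genes. The analysis plan had assumed log2 values; the same linear model was used on the scores. Standardizing each array can hide a change in overall spread, which is why other scalings were tried. Scan dates, batches and a genome build are not given in the sources used here, and no genomic coordinates are printed. For arrays the number per group limits the precision.

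Array control probe sets (115) were left out, leaving 15502. Gene symbols came from the platform annotation of 2016, updated through Entrez identifiers against the RefSeq gene table of assembly GRCz12tu, where 10711 identifiers matched and 1 symbol changed. Of the tested probe sets 10795 had 1 symbol, 135 had several and 4572 had none; the last 2 kinds entered the counts and are not named. Probe sets whose names carry _s_at, _x_at or _a_at can bind several transcripts.

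Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit with a group term, eBayes without trend), with Benjamini-Hochberg adjustment over all 15502 probe sets and a threshold of 0.05. For genes, the probe set with the highest mean over the 6 arrays stood for each of 8793 genes. A total of 36 gene lists covering ER and stress pathways, lipid metabolism and markers of larval organs and cell types was written before the data were examined, as were the tests and most of the other settings. Of 1567 symbols on these lists 986 were measured. Lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01 and adjusted over the 36 lists; camera with an estimated correlation, camera on ranks and fry (directional and mixed) were alternatives. The genes named were cdipt, the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap and whose symbols are not placeholders, the 4 members of each list with the smallest p, and hspa5, xbp1, atf6, ddit3, hsp90b1, fasn, fabp10a, apoa1a and prss1; others are said to be named after their values were seen. Of the 163 measured genes under this rule 73 passed the threshold, and 44 of these passed in each of the 6 fits that left out 1 array.

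The replicate numbers in the titles were tested as pairs. Deviations from the group means, correlated across probe sets, gave 0.20 for the replicate 1 arrays, 0.166 for replicate 2 and 0.367 for replicate 3. The numbers thus passed the rule that every pair exceed 0.1. The labels do not say what a number shares. Mutant replicate 1 with wild-type replicate 2, a crossed pair, correlated at 0.227, more than the matched pairs of either number. Mutant replicate 2 with wild-type replicate 1, at 0.167, was close to the replicate 2 pair and below the replicate 1 pair. Within a group the deviations cancel out, so likeness of the replicate 3 arrays alone raises the correlations among the other arrays. The rule could therefore not show pairing for replicates 1 and 2, and the main fit stayed unpaired, as planned. The fit with the replicate block is therefore printed beside many of the results it changes. The other settings fixed beforehand were an equal median per array, cyclic loess, removal of dim probe sets, an intensity trend with robust eBayes, array quality weights, the replicate block, each array left out, no moderation, an adjusted p of 0.01, 1 probe set per gene and the list tests above. Quantile normalization, scaling by the median absolute deviation, size thresholds of 0.5 and 1 array SD and leaving out both replicate 3 arrays were chosen after seeing the data.

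The scripts were tested on simulated data for this comparison, drawn for the same 15502 probe sets with 200 changed. They recovered 56.72% of changes of 0.3 array SD, 88.06% of 0.6 and 100% of 1.2, with 6 false calls. Both lists shifted by 0.2 were called, also with an estimated correlation, and 0 unshifted lists. The simulated genes were drawn independently of each other, so this does not test false list calls among correlated genes. In the real lists the estimated correlation reached 0.76, for ribosome biogenesis. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.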

Results

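The series profiled gene expression in whole zebrafish larvae carrying hi559, a transgenic insertion allele of cdipt, the gene for the enzyme that makes phosphatidylinositol from CDP-diacylglycerol and inositol. Embryos of heterozygous parents were raised at 28 °C and sorted by phenotype into mutants and phenotypically wild-type siblings, a group that can include heterozygous carriers. RNA of 25 larvae per sample, taken 5 days post fertilization (dpf), was hybridised to Affymetrix arrays, with 3 arrays of mutants and 3 of wild-type siblings. The comparison asks how the transcriptome differs when larvae lack cdipt function. The series title names endoplasmic reticulum (ER) stress and fatty liver as the study's subject. Each deposited value is a score in array standard deviations (array SD), the distance of a probe set from its array's median in units of the spread of all 15617 probe sets on that array. Differences are mutant minus wild type in array SD, and no fold changes are given. Nothing in the labels says that the 3 samples of a group came from separate clutches, so p-values measure the spread between these samples.

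Mutant larvae had lower levels of cdipt itself, of phototransduction genes and of genes of the absorptive intestine. They had higher levels of ER chaperone genes, of the stress-response transcription factor genes atf3 and cebpb, and of fibrinogen genes and some complement genes. The UV cone opsin gene opn1sw1 fell by 2.41 array SD (SE 0.340), the intestinal fatty acid binding protein gene fabp2 fell by 0.984 (SE 0.0875), and the ER chaperone gene hspa5 (BiP) rose by 0.708 (SE 0.0849), each from 3 arrays per group. The complement gene c4b had the largest rise among the named genes past the test, 1.36 array SD (SE 0.0553, adjusted p = 3.11e-05). Of 15502 probe sets tested with limma, 471 passed an adjusted p of 0.05, with 190 higher and 281 lower in mutants. Among these, 57 of the lower and 11 of the higher probe sets differed by at least 1 array SD.

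Expression of cdipt separated the groups on every array, in the direction of the labels. Its single probe set stood at -1.11 ± 0.116 array SD (SD, n = 3) in mutants and 0.347 ± 0.0891 (SD, n = 3) in wild-type larvae. The difference was -1.46 array SD (SE 0.0722, adjusted p = 4.89e-05 by limma). In rank, cdipt lay at percentile 14.3 of the probe sets in mutants and percentile 65.1 in wild-type larvae. An exact two-sided permutation test over the 20 relabellings gave p = 0.1, the smallest value that 3 against 3 arrays allow. Where the probes lie relative to the insertion is not given in the sources used here. Among the 21 measured genes of phosphoinositide synthesis and turnover, cdipt was the only member past the test, also when adjusted over the list alone. The list as a whole was not shifted (adjusted p = 0.849 by limma's camera, whose direction was up while the members' mean was -0.0420 array SD). The next members by p-value were pik3r3b, a regulatory subunit gene of PI 3-kinase, at 0.223 array SD (adjusted p = 0.189) and pitpnb, a phosphatidylinositol transfer protein gene, at 0.212 (adjusted p = 0.228).

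**Figure D1:**
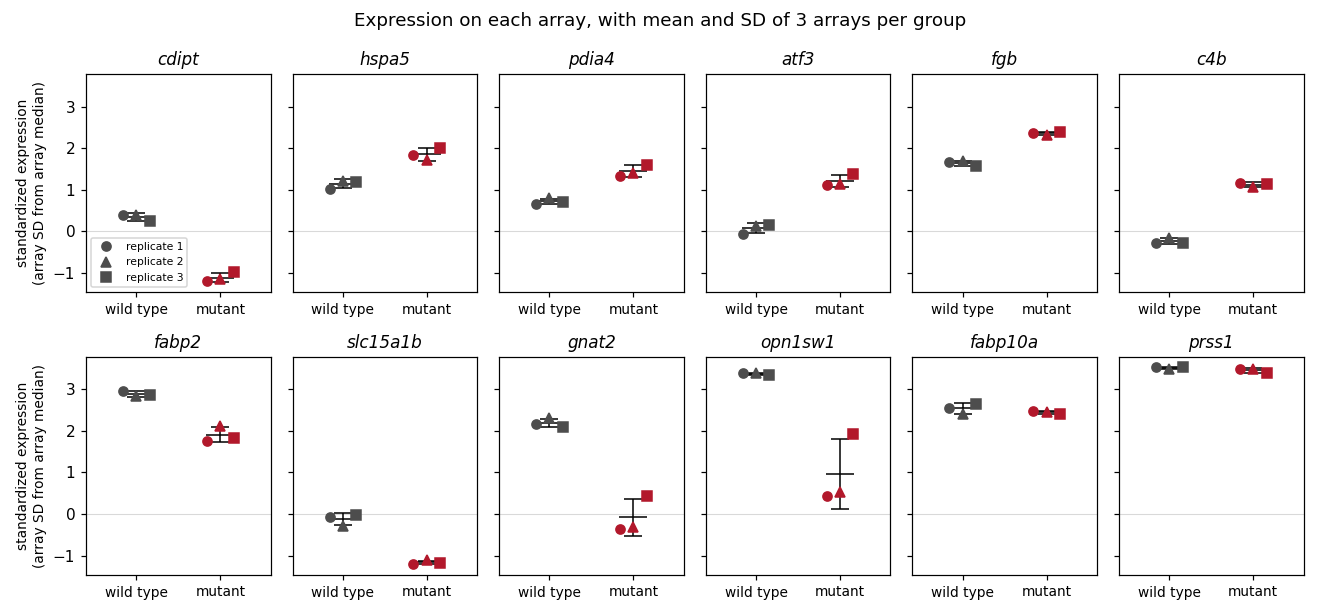
Standardized expression (array SD from the array median, vertical axis) of 12 genes on each of the 6 arrays, with wild-type larvae in grey and mutants in red, the replicate number as the symbol, and the mean and SD of 3 arrays in black. In the cdipt panel mutants lie between -1.2 and -0.978 and wild-type larvae between 0.244 and 0.408, and opn1sw1 in mutant replicate 3 lies at 1.92, above 0.429 and 0.537 in the other mutants.

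ER chaperone and folding genes were higher in mutants. Of 27 measured members, 11 rose, 0 fell and 16 did not pass the test, with a median difference of 0.204 array SD. Adjusted over the list alone, 13 rose. The protein disulfide isomerase genes pdia4 and pdia6 rose by 0.724 (SE 0.0751, adjusted p = 0.00151) and 0.518 (SE 0.0489, adjusted p = 0.000967). The chaperone genes hspa5 (adjusted p = 0.00304) and hyou1 (adjusted p = 0.00289) rose by 0.708 and 0.599. The GRP94 gene hsp90b1 rose by 0.527 (adjusted p = 0.0097, and 0.0632 without wild-type replicate 1). The list was shifted upward by camera (adjusted p = 5.86e-12), a call lost at adjusted p = 0.168 with an estimated correlation. The number of members that rose was 4 without wild-type replicate 1, 5 without mutant replicate 2, 5 without mutant replicate 3 and 6 without mutant replicate 1.

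Of 17 sensors and effectors of the unfolded protein response and integrated stress response, 2 rose, 0 fell and 15 did not pass. The transcription factor genes atf3 and cebpb rose by 1.14 (SE 0.0843, adjusted p = 0.000314) and 0.870 (SE 0.0986, adjusted p = 0.00225). The eIF2α phosphatase subunit gene ppp1r15a was at 0.407 (adjusted p = 0.0540, and 0.0378 with the replicate block). The transcription factor genes atf4b and xbp1 were at 0.211 (adjusted p = 0.0601) and 0.138 (SE 0.0487, adjusted p = 0.215). Adjusted over the list alone, 7 members rose and 1 fell. The list was shifted upward (adjusted p = 0.00234), with adjusted p = 0.168 with an estimated correlation. No probe set was named atf6 or ddit3, so these were not analysed here.

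Other secretory and protein turnover lists were shifted upward by small amounts. None of 40 ER-to-Golgi traffic genes passed the test over all genes, 1 rose with the replicate block, and 3 rose when adjusted over the list alone. Of these 40 genes, 37 lay above 0, with a median of 0.108 array SD and adjusted p = 3.57e-07 for the list (adjusted p = 0.264 with an estimated correlation). The SNARE gene ykt6 was at 0.305 (adjusted p = 0.0582, and 0.0289 with the replicate block). Among 31 genes of ER-associated degradation and the translocon, 25 lay above 0 and none passed either adjustment, with herpud1 at 0.323 (adjusted p = 0.0948) and tram1 at 0.251 (adjusted p = 0.126, and 0.0474 with the replicate block). That list had adjusted p = 0.00298 (adjusted p = 0.488 with an estimated correlation), and the call ended without mutant replicate 3 (0.0847) and with median absolute deviation scaling (0.250). Proteasome genes lay above 0 for 36 of 42 members, with none past either adjustment and 2 risen with the replicate block. Their adjusted p was 7.63e-05 (adjusted p = 0.488 with an estimated correlation, and 0.0901 with median absolute deviation scaling). Amino acid synthesis and tRNA charging genes were shifted upward with adjusted p = 0.00552 (adjusted p = 0.264 with an estimated correlation, and 0.0715 with median absolute deviation scaling). With median absolute deviation scaling the medians shrank to 0.0615 for ER-to-Golgi traffic, 0.0103 for ER-associated degradation, 0.0230 for the proteasome and 0.0423 for amino acid synthesis. The single member of that amino acid list of 26 past the test, the amino acid transporter subunit gene slc3a2a, was lower, at -0.270 (adjusted p = 0.0265, and up to 0.142, without wild-type replicate 1). With the replicate block 2 of them rose and 1 fell, as also when adjusted over the list alone. Among 36 genes of the p53 response and apoptosis, 31 lay above 0 and the pro-apoptotic gene baxa rose by 0.317 (adjusted p = 0.0177, and up to 0.103, without wild-type replicate 1). Both with the replicate block and adjusted over the list alone, 4 of these genes rose, as did 4 without wild-type replicate 3, and 0 rose without mutant replicate 1, 2 or 3 or without wild-type replicate 1. The list had adjusted p = 1.41e-05 (adjusted p = 0.168 with an estimated correlation).

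Intestinal genes were lower. Of 18 measured markers of intestinal epithelium, 12 fell, 0 rose and 6 did not pass, with a median difference of -0.587 array SD. Adjusted over the list alone, 14 fell and 1 rose, and with the replicate block 13 fell and 1 rose. The brush border peptide transporter gene slc15a1b fell by 1.03 (SE 0.0746, adjusted p = 0.000276) and the microvillus protein gene vil1 fell by 0.774 (SE 0.0642, adjusted p = 0.000566). The chitinase genes chia.1 and chia.2 were lower, at -2.14 (SE 0.204, adjusted p = 0.000986) and -1.13 (SE 0.0982, adjusted p = 0.000718). The list was shifted downward (adjusted p = 4.27e-14, and adjusted p = 0.195 with an estimated correlation). Of the 26 apolipoprotein and lipid transport genes, 3 fell and 0 rose. The fatty acid binding protein gene fabp1b.1 fell by 1.19 (SE 0.0900, adjusted p = 0.000339) and apoa4b.2 fell by 0.511 (SE 0.0627, adjusted p = 0.00344), and the other was fabp2, which is also on the intestinal list. Adjusted over the list alone, 5 of them fell. That list missed the threshold at adjusted p = 0.0501 and passed it without mutant replicate 1 (0.0439), mutant replicate 2 (0.0130) or wild-type replicate 1 (0.0493), with median absolute deviation scaling (0.00161), with dim probe sets removed (0.0369) and with a robust intensity trend (0.0491). The main HDL apolipoprotein gene apoa1a was at 0.104 (SE 0.0595, adjusted p = 0.419), a value that turned to -0.0170 with median absolute deviation scaling.

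Liver detoxification genes were lower for 4 of 16 members and higher for 0, and adjusted over the list alone 10 fell and 2 rose. The cytochrome P450 gene cyp3a65 fell by 1.12 array SD (SE 0.105, adjusted p = 0.000967) and the organic anion transporter gene slco1d1 fell by 0.414 (SE 0.0562, adjusted p = 0.00597), and the others were cyp2y3 (adjusted p up to 0.106, without wild-type replicate 1) and sult1st3 (0.0502 to 0.158 with 1 array left out). The list was shifted downward (adjusted p = 0.000133, and adjusted p = 0.228 with an estimated correlation). With the replicate block 7 fell and 1 rose, while 2 fell without mutant replicate 1, without mutant replicate 3 or without wild-type replicate 1.

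Lipid synthesis and breakdown lists had few members past the test. Of 17 fatty acid and triglyceride synthesis genes 2 fell and 0 rose. The very long chain fatty acid elongase gene elovl4b fell by 1.2 (SE 0.146, adjusted p = 0.00337) and the monoacylglycerol acyltransferase gene mogat2 fell by 0.470 (SE 0.0653, adjusted p = 0.00678). Adjusted over the list alone 3 rose and 3 fell, with the replicate block 2 rose and 3 fell, and the list was not shifted (adjusted p = 0.476). No probe set was named fasn. Fatty acid oxidation genes were below 0 for 22 of 24 members, with adjusted p = 0.000299 for the list (adjusted p = 0.446 with an estimated correlation). Over all genes and over the list alone 1 of them fell, the peroxisomal β-oxidation gene hsd17b4, at -0.383 (adjusted p = 0.0470, and 0.0530 to 0.209 with 1 array left out). Only 1 of the 2 probe sets of hsd17b4 passed. Of 20 other phospholipid synthesis genes 2 fell, also when adjusted over the list alone, and the list was not shifted (adjusted p = 0.435). They were the choline phosphotransferase gene chpt1 at -0.434 (adjusted p = 0.0103, and 0.0680 without wild-type replicate 1) and the acyltransferase gene agpat2 at -0.295 (adjusted p = 0.0446, and 0.0541 to 0.182 with 1 array left out). Among 12 cholesterol synthesis genes the sterol reductase gene dhcr7 fell by 0.326 (adjusted p = 0.0414, and up to 0.195, without wild-type replicate 1), also when adjusted over the list alone. That list had adjusted p = 0.379.

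Phototransduction genes were among the largest falls of probe sets with 1 gene symbol. The largest fall of all, -2.47 array SD, was of a probe set without a symbol. Of 25 measured photoreceptor and retina markers, 18 fell, 0 rose and 7 did not pass, with a median of -0.955 array SD. Adjusted over the list alone, 21 fell and 1 rose. The cone transducin gene gnat2 fell by 2.27 (SE 0.191, adjusted p = 0.000581) and the guanylate cyclase activator gene guca1c fell by 2.04 (SE 0.0925, adjusted p = 3.75e-05). The cone phosphodiesterase genes pde6c and pde6ha were lower, at -2.11 (SE 0.145, adjusted p = 0.000209) and -2.17 (SE 0.0792, adjusted p = 2e-05). The blue and green cone opsin genes opn1sw2 and opn1mw1 were lower, at -2.09 and -2.07. The rod transducin subunit gene gngt1, on no list, fell by 2.12 (SE 0.201, adjusted p = 0.000967). Tandem opsin copies are close in sequence, so a probe set can bind transcripts of a neighbour. The list was shifted downward (adjusted p = 2.16e-24, and adjusted p = 0.168 with an estimated correlation). Mutant replicate 3 lay above both other mutants for 13 of the 18 genes that fell. Lens genes lay below 0 for all 9 members, with a median of -0.108 and adjusted p = 0.00187 (adjusted p = 0.352 with an estimated correlation). Over all genes and over the list alone 1 of them fell, the crystallin gene cryaa, at -0.265 (adjusted p = 0.0491, and 0.0656 to 0.184 with 1 array left out).

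**Figure D2:**
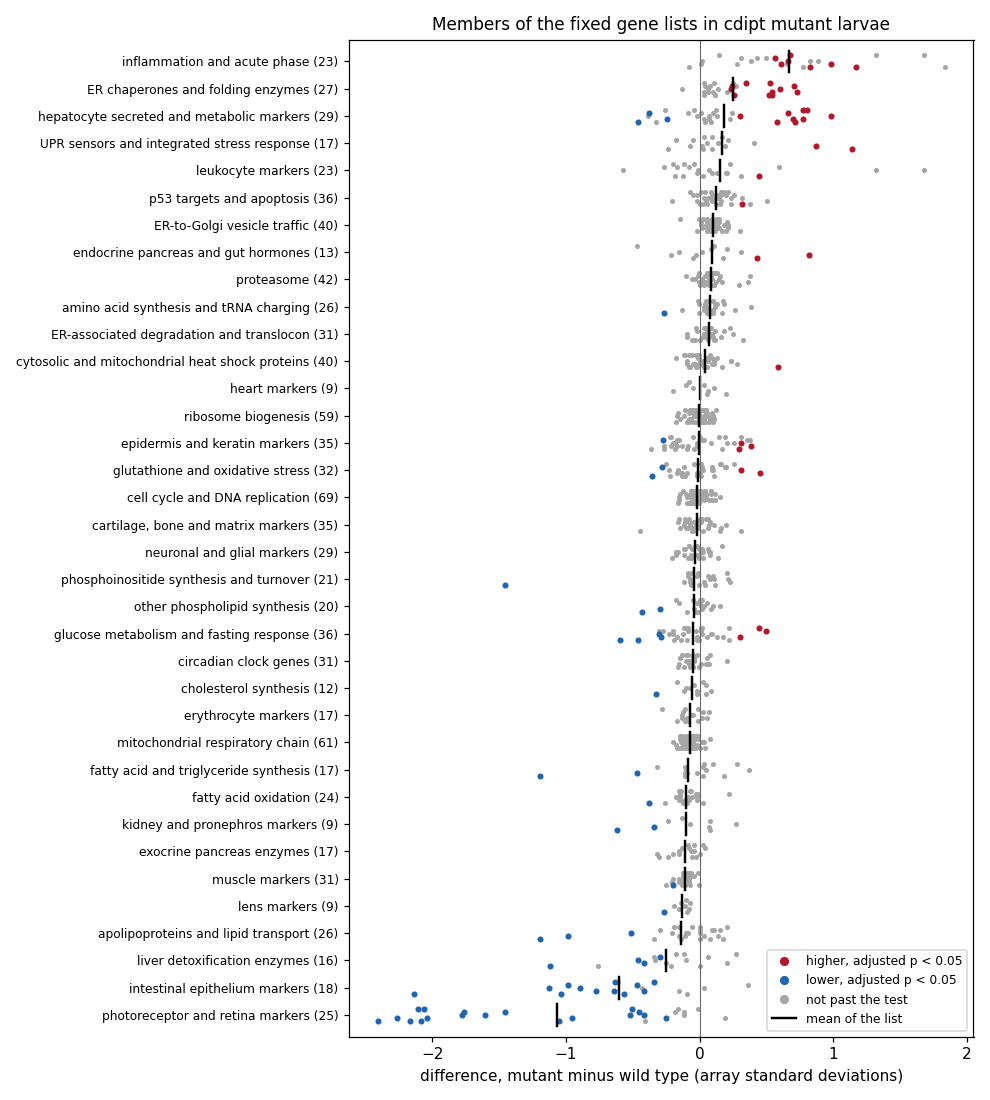
Difference between mutant and wild-type larvae (array SD, horizontal axis) for each measured member of the 36 gene lists, ordered by the mean of the list (black bar), with the number of measured members in parentheses. Red and blue points passed an adjusted p of 0.05 as higher or lower and grey points did not. Photoreceptor markers reach -2.41, while 11 of 27 ER chaperone genes are red.

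Of 29 hepatocyte markers 9 rose, 3 fell and 17 did not pass, and 10 rose and 6 fell adjusted over the list alone. The fibrinogen chain genes fgb and fga rose by 0.711 (SE 0.0505, adjusted p = 0.000254) and 0.806 (SE 0.0939, adjusted p = 0.00266). The complement genes c3a.1 and c9 rose by 0.982 (SE 0.0924, adjusted p = 0.000967) and 0.660 (SE 0.0737, adjusted p = 0.00216). Only 1 of the 2 probe sets of c3a.1 passed. The liver fatty acid binding protein gene fabp10a was at -0.0885 (SE 0.0663, adjusted p = 0.534). Camera gave an upward shift (adjusted p = 0.000483, and adjusted p = 0.168 with an estimated correlation). The 3 members that fell were fetub, hpda and hnf4a, named after their values were seen. That count was 1 without mutant replicate 1, 0 without mutant replicate 2, 1 without mutant replicate 3, 0 without wild-type replicate 1 and 1 without wild-type replicate 3.

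Inflammation and acute phase genes were higher. Of 23 members 7 rose, 0 fell and 16 did not pass, with a median of 0.653 array SD. With the replicate block 15 rose, and 15 also adjusted over the list alone. The cytokine signalling genes socs3b and stat3 rose by 1.17 (SE 0.0997, adjusted p = 0.000615) and 0.563 (SE 0.0643, adjusted p = 0.00237), and c3a.1 and c9 are members of this list too. Its shift had adjusted p = 7.78e-13 (adjusted p = 0.264 with an estimated correlation). Mutant replicate 3 lay above both other mutants for 19 of the 23 genes, and 13 rose when both replicate 3 arrays were left out. The AP-1 genes junba and junbb, on no list, rose by 1.1 (SE 0.116, adjusted p = 0.00163) and 0.846 (SE 0.0792, adjusted p = 0.000967). The rise of socs3a, 0.823 (adjusted p = 0.0153), was lost without mutant replicate 1 (0.0501) or wild-type replicate 2 (0.0572). The complement gene c7b rose by 0.962 (adjusted p = 0.0451) and the haem-binding hemopexin gene hpxb by 0.921 (adjusted p = 0.0386). Both calls held without mutant replicate 2 or 3 and were lost without any of the other arrays, with adjusted p up to 0.196 and 0.160, without wild-type replicate 1. Leukocyte markers did not pass as a list (adjusted p = 0.311), but did with dim probe sets removed (0.0277, upward) and without both replicate 3 arrays (0.0241). Their counts were 1 of 23 members risen, 0 without mutant replicate 1 or wild-type replicate 1 or 2, 2 without mutant replicate 3 or wild-type replicate 3, 5 without both replicate 3 arrays, 3 with the replicate block, and 6 risen and 4 fallen adjusted over the list alone. The member that rose was the scavenger receptor gene marco, at 0.443 (adjusted p = 0.0448, and up to 0.20, without wild-type replicate 1).

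Single genes of the endocrine pancreas passed the test, and none of the exocrine pancreas did. Of 17 exocrine pancreas genes 0 passed over all genes or adjusted over the list alone, and 2 fell with the replicate block, cel.1 at -0.308 (adjusted p = 0.0205) and cpa4 at -0.319 (adjusted p = 0.0102). The trypsin gene prss1 was at -0.0667 array SD (SE 0.0492, adjusted p = 0.529), a sign that turned with cyclic loess (0.0248) and quantile normalization (0.00428). The list was shifted downward (adjusted p = 0.0268, and adjusted p = 0.706 with an estimated correlation). That call ended without mutant replicate 3 (0.50), wild-type replicate 1 (0.108) or wild-type replicate 2 (0.0687) and with cyclic loess (0.387) or quantile normalization (0.394). In mutant replicate 3, 16 of the 17 genes lay below both other mutants. Of 13 endocrine pancreas and gut hormone genes 2 rose, and 5 rose and 3 fell adjusted over the list alone. With the replicate block 3 rose and 1 fell, among them the somatostatin gene sst1.1 at 0.311 (adjusted p = 0.0492). The somatostatin gene sst2 rose by 0.429 (SE 0.0582, adjusted p = 0.00597) and the glucagon gene gcga by 0.818 (SE 0.153, adjusted p = 0.0298, and up to 0.150, without wild-type replicate 1). A single member rose without mutant replicate 1 or without wild-type replicate 1, 2 or 3. With 1 array left out 0 to 2 members fell, and without both replicate 3 arrays 2 rose and 2 fell. The list had adjusted p = 0.101.

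Muscle genes lay below 0 for all 31 members, with a median of -0.109 array SD and adjusted p = 9.65e-06 (adjusted p = 0.488 with an estimated correlation, and 0.0648 with quantile normalization). The median shrank to -0.0394 with cyclic loess and -0.0443 with quantile normalization, and was -0.208 with median absolute deviation scaling. Over all genes and over the list alone 1 of them fell, the troponin gene tnnt3a, at -0.199 (adjusted p = 0.0479, 0.0610 with the replicate block, and 0.0618 to 0.197 with 1 array left out). Mitochondrial respiratory chain genes lay below 0 for 57 of 61 members with none past either adjustment. That list had adjusted p = 3.20e-06 (adjusted p = 0.228 with an estimated correlation, and 0.216 with quantile normalization). Its median was -0.0663, and -0.0296 with cyclic loess, -0.0186 with quantile normalization and -0.161 with median absolute deviation scaling. Of 9 kidney genes 2 fell, 3 fell and 1 rose adjusted over the list alone, and the list had adjusted p = 0.199. The sodium pump subunit gene atp1a1a.4 fell by 0.621 (SE 0.0488, adjusted p = 0.000423), and cdh17 fell by 0.340 (adjusted p = 0.0090), a call lost without mutant replicate 1 (0.0501) or wild-type replicate 1 (0.0576).

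Of 36 glucose and fasting genes 3 rose and 4 fell, 4 rose and 6 fell adjusted over the list alone, and the list had adjusted p = 0.204. The gluconeogenic gene fbp1b fell by 0.597 (SE 0.0676, adjusted p = 0.00225), and pfkfb1, hpda and pck2 also fell, while vegfaa, igfbp1a and pfkfb3 rose. Of these, hpda, pck2 and pfkfb3 were named after their values were seen. The counts were 0 higher and 1 lower without mutant replicate 1 or wild-type replicate 1, 0 higher and 2 lower without mutant replicate 3, 1 lower without mutant replicate 2 and 2 lower without wild-type replicate 3. Of 32 glutathione and oxidative stress genes 2 rose and 2 fell, 4 rose and 6 fell adjusted over the list alone, and the list had adjusted p = 0.535. The superoxide dismutase gene sod1 fell by 0.357 (SE 0.0508, adjusted p = 0.00755, and 0.0536 without wild-type replicate 1). The other calls, txnb and gpx1b higher and prdx2 lower, were each lost in at least 5 of the 6 fits without 1 array. Of 35 epidermis genes s100a10b, anxa2a and cdh1 rose and icn2 fell, 7 rose and 4 fell adjusted over the list alone, and the list had adjusted p = 0.770. With the replicate block 7 of them rose and 3 fell, at most 1 rose with any 1 array left out, and 3 fell without wild-type replicate 2. Of 40 heat shock genes 1 rose, also when adjusted over the list alone, and 4 rose with the replicate block, with adjusted p = 0.396 for the list. It was hsp70.3, at 0.582 (SE 0.0926, adjusted p = 0.0132), lost without mutant replicate 1 (0.0630) or mutant replicate 3 (0.0532).

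No member passed either adjustment in the lists of cell cycle (69 genes, adjusted p = 0.408), ribosome biogenesis (59, adjusted p = 0.958), cartilage and matrix (35, adjusted p = 0.645) or circadian clock (31, adjusted p = 0.204). The same held for neurons and glia (29, adjusted p = 0.271), erythrocytes (17, adjusted p = 0.0876, 0.0478 with the replicate block, 0.0206 with array quality weights and 0.0385 on ranks) and heart (9, adjusted p = 0.821). Neurons and glia passed with median absolute deviation scaling (0.00956). Their member tubb5 has 2 probe sets, of which 1 was called lower, but not the brighter one that stood for the gene. Without wild-type replicate 3, cell cycle (0.0135), neurons and glia (0.0342), cholesterol synthesis (0.00823) erythrocytes (0.0450) and ribosome biogenesis (0.0168, upward) passed, and without mutant replicate 3 ribosome biogenesis (0.00136, downward) and erythrocytes (0.0102) did. At an unadjusted p of 0.05, limma called 2615 of all 15502 probe sets.

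Camera with a preset correlation of 0.01 called 17 of the 36 lists, 9 higher and 8 lower, and 0 with an estimated correlation, while limma's fry, which does not compare a list with other genes, called 12 in 1 direction. The 471 probe sets, each with all 3 mutants beyond all 3 wild-type arrays, a separation that chance gives 10% of probe sets, became 727 with the replicate block (361 higher, 366 lower), 227 without wild-type replicate 1, 272 without mutant replicate 1, 296 without mutant replicate 2 and 310 without mutant replicate 3.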

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

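Quantile normalization, median absolute deviation scaling, the size thresholds and the removal of both replicate 3 arrays were chosen after seeing the data. The 471 calls kept their sign in each refit that tested all of them. Where arrays were left out or weighted this was fixed in advance, since all 3 mutants lay beyond all 3 wild-type arrays. The robust trend and the replicate block leave the differences unchanged, so only the rescaled fits could have turned a sign. Expression of cdipt stayed lower and past the threshold in each refit that tested it, between -1.52 and -1.41 array SD when 1 array was left out. Equal medians, cyclic loess, a robust trend, quantile normalization, median absolute deviation scaling, 1 probe set per gene and the removal of dim probe sets each moved the count of probe sets by less than 1.5 times.

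The count of 471 (190 higher, 281 lower) was 3923 (1743 higher, 2180 lower) with array quality weights, which ran from 0.234 for wild-type replicate 3 to 5.40 for wild-type replicate 1. It was 33 (6 higher, 27 lower) without moderation, 227 (71 higher, 156 lower) at an adjusted p of 0.01, 213 (76 higher, 137 lower) with a difference of at least 0.5 array SD, and 68 (11 higher, 57 lower) with at least 1. Stricter thresholds lower a count by construction; the cause was not tested for the others. It was 753 (360 higher) without both replicate 3 arrays. Leaving out 1 array gave 227 to 479 in all, 73 to 187 higher and 154 to 292 lower, from fewer samples. The planned thresholds of fold change were not run, since the deposited scale gives no fold.

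Paired by number, the replicate block gave 727 probe sets, of which 361 were higher, and included 463 of the 471. It made 17 named genes pass and 1 fail, and made the erythrocyte list pass; it changed no other call of a named gene or list. The lists called, 17 (9 higher, 8 lower), were 0 (0 higher, 0 lower) with an estimated correlation and 28 by fry in mixed direction. Quantile normalization gave 5 lower. The list of the unfolded protein and integrated stress responses had an estimated correlation of -0.0358, below the preset 0.01, and its call was lost as well. For the hepatocyte list the estimate was 0.0135, close to the preset. A higher correlation between genes therefore does not account for every lost call, and the causes were not otherwise tested. Leaving out 1 array gave 16 to 22 lists, 8 to 10 higher and 7 to 12 lower.

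Signs turned only for list means near 0 and for 2 genes, none of them called in the full fit; the cause was not tested. With cyclic loess the means were 0.0220 for epidermis and 0.00599 for glutathione, and prss1 was 0.0248. Quantile normalization gave 0.0310 for epidermis, 0.0134 for glutathione, 0.00218 for cartilage and 0.00428 for prss1. Scaling by the median absolute deviation gave -0.00361 for heat shock, -0.0118 for heart and -0.0170 for apoa1a. Array quality weights gave 0.00302 for cell cycle and -0.0124 for heart, and removing both replicate 3 arrays gave 0.0131 for cartilage. Leaving out 1 array gave -0.0507 to 0.0199 for cell cycle, -0.0340 to 0.0282 for epidermis, -0.0273 to 0.00367 for glutathione, -0.0293 to 0.0250 for heart and -0.0792 to 0.0542 for ribosome biogenesis.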

Other observations

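Among the tests below, those on mutant replicate 3, on the hepatocyte share and on the scaling of the arrays, by quantile normalization, were chosen only after the result was seen. Acute phase, complement and clotting genes collected after the largest rises had been seen numbered 28, of which 15 rose and 0 fell; angiotensinogen gene agt was at 0.773 (adjusted p = 0.00873) and c6.2 at 0.788 (adjusted p = 0.00167), while hp was at 0.00876 and serpina1l at 0.0685. That set is not independent evidence of its direction.

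Both replicate 3 arrays stood apart from their groups, with root mean square deviations from the group mean of 0.0899 in mutants and 0.108 in wild-type larvae, against 0.0588 to 0.0796 on the other arrays. Gene irg1l, picked after its values were seen, was raised on both, at 2.47 against 1.74 and 1.4 in mutants and at 1.34 against -0.576 and -0.674 in wild-type larvae. Other genes were high in mutant replicate 3. The matrix metalloproteinase gene mmp9, picked after its values were seen, was at 2.45 array SD there, against 0.854 and 0.50 in the other mutants. The related gene mmp13a was at 2.76, against 1.26 and 0.917. Neither passed the test (adjusted p = 0.179 and 0.0738), and mmp13a did with the replicate block (0.00991). The serum amyloid gene saa, named after its values were seen, was at 1.3 against -0.324 and -0.50. Across the inflammation list the median shift of mutant replicate 3 from the other mutants was 0.346 (bootstrap 95% interval 0.20 to 0.630), and across exocrine pancreas genes -0.157 (-0.264 to -0.105). These intervals and those below resample genes and not arrays. They treat the genes of a list as independent and do not measure the spread between samples. Of 115 array control probe sets 0 were higher and 1 was lower in mutants. The lower 1 is named for a zebrafish transcript and not a spike, and was at -1.37 array SD (adjusted p = 0.000877 by limma, with the controls included).

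The fall of photoreceptor transcripts was weighed against smaller eyes and against the scaling of the arrays. If lens and retina were reduced alike, the lens median would lie at or below -0.478, the middle between 0 and the photoreceptor median, but it was -0.108 (95% interval -0.189 to -0.0832), which argues against an equal loss of both. After quantile normalization the photoreceptor median was 0.996 times its value before. This cannot decide on the scaling, since it was run on scores already brought to 1 median and 1 standard deviation. Their quartiles were also close, at -0.695 to -0.635 and 0.579 to 0.618, so values could move little. Fewer or less mature photoreceptors, or lower transcription in each, stay open as effects of genotype or of a delay in development; no test here separates them.

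Mutant replicate 3 was above the other mutants in photoreceptor transcripts, with a median shift of 0.159 over the list (95% interval 0.0354 to 0.383). An array effect shared by both replicate 3 arrays would raise wild-type replicate 3 too, but its median shift was -0.0816 (95% interval -0.160 to 0.0895). Taken gene by gene, the mutant shift minus the wild-type shift had a median of 0.226 (95% interval 0.0204 to 0.372). Each shift rests on 1 array. Wild-type larvae mixed into that pool cannot be told apart from a milder eye phenotype. The 49 genes outside the list that were lower by at least 0.7 were shifted by 0.139 (0.0544 to 0.187), as mixing would give. They include the phototransduction gene gngt1, so a milder eye phenotype could raise this value too. The 12 intestinal genes that fell were shifted by -0.0164 (-0.0928 to 0.0365). Expression of cdipt was at -0.978 in mutant replicate 3, against -1.20 and -1.15, a direction that mixing would give. In wild-type replicate 3 it was at 0.244, against 0.408 and 0.388. Over the 18 photoreceptor genes that fell, the median shift was 0.270 in mutant and -0.146 in wild-type replicate 3. Both replicate 3 arrays thus lay toward the other group, and with 1 array each this does not decide on mixing. The 49 genes higher by at least 0.5 were shifted further up, by 0.134 (0.0960 to 0.205), which mixing alone would not give. An earlier rule for this test counted that rise as ruling mixing out. It was replaced after the value was seen, since a stronger inflammatory response in the same pool could raise these genes despite mixing.

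The rise of acute phase, complement and clotting transcripts was weighed against a larger share of hepatocytes. That would raise all hepatocyte genes, and the 29 members of the hepatocyte list had a median of 0.0872 (95% interval 0.00876 to 0.245), against 0.593 for the set (0.112 to 0.741). All but 11 of these 29 belong to the set whose rise is to be explained. A median above 0 therefore follows in part from that rise and does not speak for a larger share. Members of the list went both ways, 9 higher and 3 lower. A larger share alone would not lower members, but the number that fell was 0 to 3 with 1 array left out. A larger share joined by changes within hepatocytes cannot be told apart from such changes alone. Comparisons with the set are printed but decide nothing, since the set was collected after the rises had been seen. With both resampled together, the list median minus the set median was -0.506 (-0.670 to -0.0430), and minus 0.5 times the set median it was -0.209 (-0.318 to 0.0275). The 11 list members outside the set had a median of -0.247 (-0.383 to -0.0180), which leaves out the members that rose. The abundant hepatocyte transcripts tfa and rbp4, named after their values were seen, were at -0.0427 and -0.0180, and the liver detoxification list had a median of -0.235. The rule for this test was changed several times after values had been seen. A response of the liver to inflammation or to ER stress is a hypothesis that these arrays also leave open.

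Other splits of the 6 arrays into 3 and 3 number 10 with the real split, too few for a share under 0.05. The real split called 471 probe sets, and the highest of the others 0, so 1 of 10 splits reached the real count; the 3 other splits that part all 3 pairs also called 0. For the gene lists the real split called 17 and the highest of the others 17, so 2 of 10 splits reached that count, and the others called 5 to 17. The 17 were also reached with mutant replicates 1 and 3 and wild-type replicate 3 on a side. The mean shift of a list was largest in the real split for 15 of the 17 lists called. The exceptions were ER-associated degradation and exocrine pancreas. These 17 were called for their shift in the real split, so the count follows in part from that choice. Over all 36 lists tested it was 19. Margins differed, from 1.07 array SD against at most 0.499 in another split for photoreceptors to 0.0815 against 0.0813 for the proteasome. The count therefore does not speak for the smaller shifts.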
